A study of Homo sapiens with 6 samples.

How the data were processed

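RNA of HepaRG cells, untreated, was measured in 6 libraries, 3 of wild-type cells and 3 of cells with a functional PXR knockout. Groups and replicate numbers were taken from the labels, which name the wild type as the control. Per the labels' protocols, libraries were made from total RNA with a stranded mRNA kit and sequenced as paired-end reads. The submitters' processing notes name FastQC, Trim Galore, Bowtie2, edgeR and limma with the hg38 build; versions, the annotation release and the gene filter are not given in the sources used here. Sample titles begin with RSEM, a program that estimates counts for genes and shares ambiguous reads between them.

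The deposited table holds 16673 genes in 6 columns of a normalized signal on a linear scale, although it is named for log2 CPM values. In each column of the deposited signal every value was a multiple of a hundredth of a step worth 1 read, within 0.05 of a hundredth, which is how estimated counts with decimals look after division by a scaled library size. The values are therefore called scaled CPM here. Columns summed to 936409, 947974 and 942139 in wild type and to 1028470, 1042826 and 1039165 in the knockout, so a factor per library had been applied. The step gave the estimated depth of each library, from 11359209 to 33393110 reads, with 1 read worth 0.031 to 0.082 CPM. Only 67.9% to 76.6% of the values under 20 reads were whole reads within 0.006 of a read, so no test for whole counts was applied. Estimated counts share reads between near-identical genes, and the levels of such genes are uncertain.

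The 14 rows of second pseudoautosomal copies were left out, and 21 symbols that had turned into dates were restored from the gene identifier. Of 16659 remaining identifiers, 16608 matched GENCODE 29 on GRCh38, which gave coordinates and gene types. In all, 3 genes were at 0 in all 6 libraries. Small RNA genes, 94 in number, took 6.15%, 6.19% and 5.61% of the signal in wild-type libraries and 4.13%, 5.75% and 4.39% in knockout libraries.

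The design fixed before the data were examined assumed log2 values. As the values are linear, log2(scaled CPM + 0.5) was tested instead with limma 3.58.1 in R 4.3.3 (linear model by group, empirical Bayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Genes were kept where scaled CPM was above 1 in at least 3 of the 6 libraries, whatever their group. Fold changes are on the log2(scaled CPM + 0.5) scale, which understates the change of low genes. Gene lists, 29 in all and fixed before the data were examined, were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 28 lists with at least 5 tested genes, and again with an estimated correlation. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction, passed 27 of the 28 lists. Fry compares a list with no change rather than with other genes, and 79.9% of all tested genes passed the threshold. It also passed the stellate and mesenchymal markers, of which 6 rose and 7 fell (fry adjusted p = 3.9e-05). Its calls therefore do not set a list apart from other genes. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

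Genes were named by a rule fixed beforehand. It took NR1I2; the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 value of at least 3 and no overlap of the groups; the up to 2 largest rises and 2 largest falls of each list; and a fixed set of genes that includes CYP3A4, CYP2B6, CYP2C8, ABCB1, UGT1A1, NR1I3, ALB and KRT19. Some genes that the rule takes are not reported here. Genes named outside this rule, RN7SK and some in the closing section, were chosen after their values were seen. XIST and Y-linked genes were not reported.

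Replicates were compared before averaging. A mean chi-square per gene on the estimated reads of pairs within a group lay between 2.23 and 9.73, so no pair agreed within sampling noise over all genes. The median over genes was 0.63 to 0.91, which is also above the median that sampling noise alone gives for this statistic. A typical gene therefore varied more than sampling noise, and the much higher means rested on part of the genes. Each library was counted as 1 replicate, although this spread does not show separate cultures. The fit was tested on simulated data for this comparison over 15891 genes, with 50 genes changed by 1.5-fold and 49 each by 2-, 4- and 8-fold. It recovered 92% of the 1.5-fold changes and 100% of those of 2-, 4- and 8-fold, with 7 false calls among 200 calls. It called the changed list and 0 of 27 random lists. Simulated genes were independent, had a fixed dispersion of 0.005 and were mostly unchanged, while 79.9% of genes passed in the real data. The simulation therefore does not test list calls on correlated genes or the scaling between libraries.

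Alternatives fixed beforehand were the replicate number as a block, no filter and a filter of 2 CPM, a pseudocount of 1, centring on library medians, quantile normalization, no trend, a robust trend, library weights, leaving out each library, and camera with an estimated correlation. Alternatives added after seeing the data were a pseudocount of 0.1, limma's voom weights on estimated reads, reads thinned to the shallowest library, scaling to equal sums over all genes, the same without small RNA genes, correction for the share of small RNA genes with the deposited factor kept, and taking out the median change of each 20 Mb window of the genome.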

Results

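HepaRG is a human liver cell line that the labels call a hepatic stem cell line. The pregnane X receptor (PXR) is a nuclear receptor that many drugs bind and that switches on genes of drug metabolism; it is encoded by NR1I2. RNA of untreated cells was sequenced in 3 wild-type libraries, named as the control group, and in 3 libraries labelled as a functional PXR knockout. In what follows, knockout means the libraries with that label. The values step in hundredths of a read, which gave estimated depths of 11359209, 19803478 and 20945994 reads for wild-type libraries 1 to 3 and of 33387989, 28154914 and 33393110 reads for knockout libraries 1 to 3. All 3 knockout libraries were therefore deeper than all 3 wild-type libraries. RN7SK, a small nuclear RNA without a poly(A) tail, took 2.08% to 3.03% of the signal, although the labels name an mRNA kit. Levels are in scaled CPM, reads relative to a scaled library size. Errors are the SD over n = 3 libraries for levels and the standard error (SE) for log2 fold changes, which are knockout minus wild type. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

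The comparison addresses how the transcriptome of untreated HepaRG cells labelled as a PXR knockout differs from that of wild-type cells. It cannot separate loss of PXR function from other differences between the cells of each group. The targeted gene, NR1I2 (ENSG00000144852.17, chromosome 3, 119780484 to 119818485 in GRCh38), was higher in the knockout. Its level was 8.24, 7.04 and 7.60 CPM in wild-type libraries 1 to 3 and 13.1, 13.4 and 14.3 CPM in knockout libraries 1 to 3. The means were 7.63 ± 0.60 and 13.6 ± 0.62 (SD, n = 3 each), a log2 fold change of 0.80 ± 0.084 (SE) with a limma adjusted p of 6.8e-07. A value summed over the whole gene does not show whether the transcript still encodes a working receptor, so it does not check a functional knockout.

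Genes for hepatocyte secreted proteins and for complement and coagulation rose in the knockout as groups, and so did targets of p53, while genes of the cell cycle fell; their counts and tests are given by list further on. Albumin, the main plasma protein made by hepatocytes, went from 867 ± 36.1 to 32829 ± 511 CPM (SD, n = 3 each). MDM2, a p53 target that encodes the ubiquitin ligase for p53, went from 179 ± 6.51 to 2993 ± 39.2 CPM. NQO1, which encodes a quinone reductase, fell from 633 ± 8.77 to 1.05 ± 0.12 CPM, the largest fall among the genes named by rule. These differences were far larger than the spread between replicates. The lowest correlation of log2 values was 0.995 within wild type and 0.997 within the knockout, and between the groups correlations ran from 0.869 to 0.871.

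**Figure D1:**
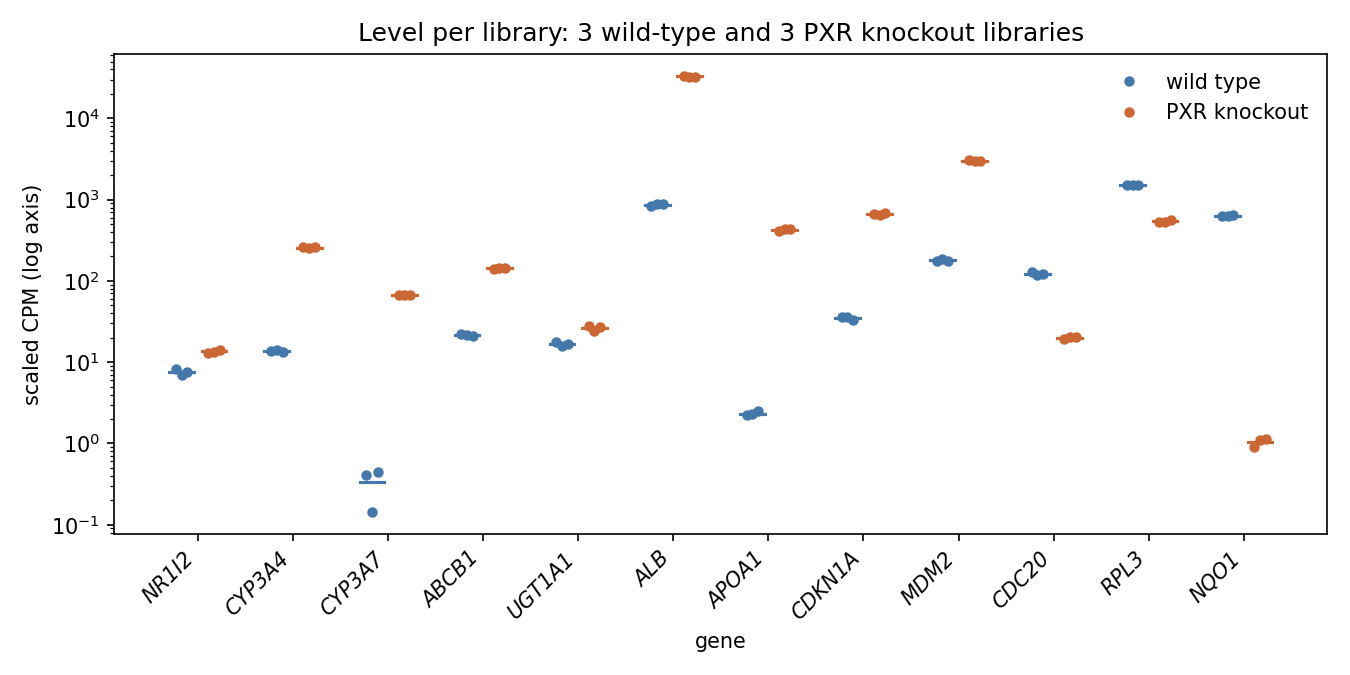
Level of 12 genes in each library, in scaled CPM on a log axis; points are the 3 wild-type and 3 knockout libraries and short lines are group means. The 2 groups do not overlap for any of these genes, with CYP3A4 at 13.7 against 257 CPM, MDM2 at 179 against 2993 CPM and NQO1 at 633 against 1.05 CPM.

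Of 16219 genes tested with limma, 12960 (79.9%) had an adjusted p under 0.05. Of these, 6534 were higher and 6426 lower in the knockout, and 3686 changed by at least 2-fold (2050 higher, 1636 lower). When libraries were scaled to equal sums, which undoes the deposited factor per library, the split became 5346 higher and 7715 lower, with the median log2 change of all genes at -0.12 in place of 0.01; when only the share of small RNA genes was corrected for, it was 6368 and 6573. Rises of at least 8-fold were seen for 371 genes and falls of that size for 148. The groups did not overlap at 13107 genes, where chance gives 10% of genes for 3 libraries against 3. The median SE of the log2 fold change was 0.064, and the median absolute log2 change of the genes past the threshold was 0.61.

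**Figure D2:**
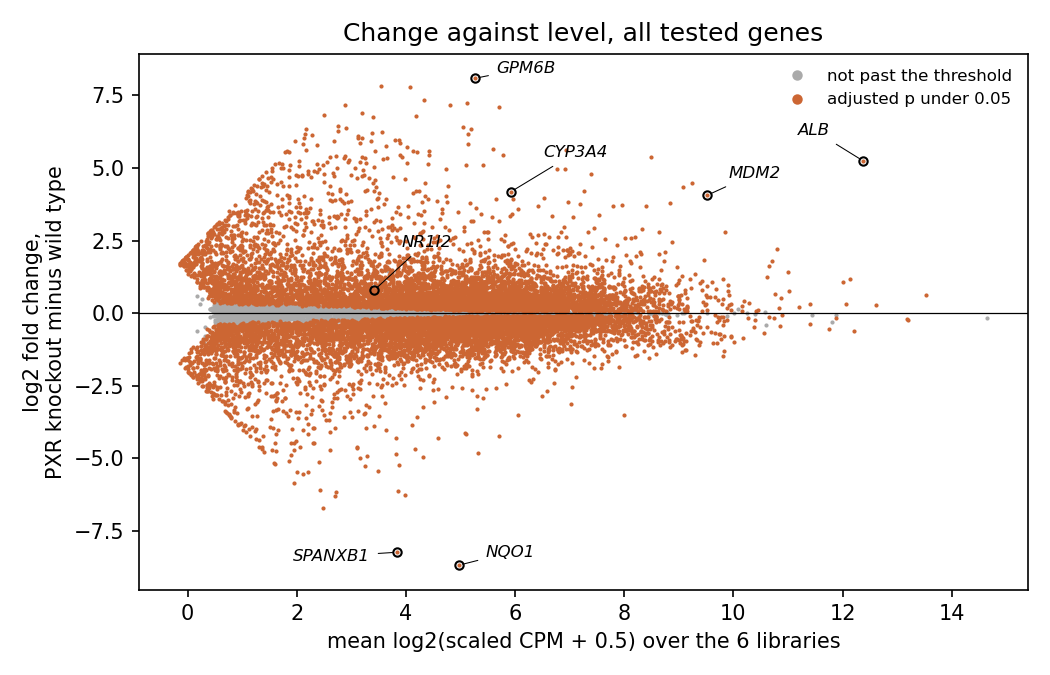
Log2 fold change (knockout minus wild type) of each tested gene against its mean log2(scaled CPM + 0.5) over the 6 libraries; orange points have an adjusted p under 0.05 and grey points do not. Of 16219 genes, 12960 are orange, and the labelled genes range from a rise of 8.09 for GPM6B to -8.68 for NQO1.

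Among the 10 largest rises were genes of the lists of secreted proteins and of complement and coagulation. GPM6B (chromosome X, 13771031 to 13938638), which encodes a membrane glycoprotein, led on the log2(scaled CPM + 0.5) scale. Its levels were 1.85 ± 0.43 against 633 ± 22.8 CPM and its log2 fold change was 8.09 ± 0.094. That scale understates more the rises of HABP2 and HPX, which had lower wild-type means of 0.29 and 0.63 CPM. HABP2, a protease of plasma, rose by 7.83 ± 0.14 and HPX, the plasma carrier of heme, by 7.80 ± 0.082. UGT2B4, a glucuronosyltransferase, rose by 7.34 ± 0.071. The apolipoprotein genes APOA1 and APOC3 rose by 7.23 ± 0.049 and 7.17 ± 0.071, and vitronectin (VTN) by 7.11 ± 0.069. FGL1, KNG1 and SERPINC1, for a fibrinogen-like protein, kininogen and antithrombin, rose by 6.90 ± 0.094, 6.81 ± 0.064 and 6.77 ± 0.093. Wild-type levels of HABP2 and FGL1 rested on 18 estimated reads each over the 3 libraries.

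The largest falls were in genes of different kinds. NQO1 (chromosome 16, 69706996 to 69726951) fell by 8.68 on the log2 scale (SE 0.057). SPANXB1, a member of a family expressed in sperm and some tumours, fell from 246 ± 3.55 to 0.35 ± 0.27 CPM; its reads may be shared with near-identical copies, which leaves its level uncertain. The fatty acid receptor gene CD36 fell from 138 ± 7.25 to 1.29 ± 0.038 CPM. The cytokine gene MIF fell from 120 ± 7.45 to 1.24 ± 0.24 CPM and lies on chromosome 22, where the median log2 change of all tested genes was -0.77. NES, EPHA7, NLGN4X and KCNQ3, genes best known from neural tissue, had log2 changes of -5.42, -5.25, -5.24 and -4.92. OXCT1, a ketone body utilisation enzyme, fell from 49.99 ± 2.38 to 1.09 ± 0.22 CPM, and the transporter gene SLC47A2 from 109 ± 3.40 to 3.07 ± 0.078 CPM.

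Genes commonly described as induced through PXR were higher in the knockout. Of 26 measured, 24 rose, 1 fell and 1 did not pass the test, with a median log2 change of 1.94 (camera adjusted p = 1.8e-09; adjusted p = 0.0154 with an estimated correlation). CYP3A4 (chromosome 7, 99756960 to 99784265), the main drug-oxidising enzyme of adult liver, rose from 13.7 ± 0.39 to 257 ± 4.80 CPM (log2 4.18 ± 0.036, limma adjusted p = 2.6e-18). CYP3A7, the fetal form, rose from 0.34 ± 0.17 to 67.4 ± 0.20 CPM. ABCB1, the drug efflux pump, rose from 21.6 ± 0.73 to 144 ± 2.33 CPM. Rises to lower levels were those of CYP2C8 (0.66 ± 0.18 to 4.53 ± 0.53 CPM), CYP2B6 (0.092 ± 0.090 to 3.50 ± 0.29 CPM) and UGT1A1 (16.8 ± 1.10 to 26.4 ± 1.69 CPM). UGT1A1 shares exons with the other UGT1A genes, and CYP2B6 rested on 6 wild-type reads, so both values are uncertain. AKR1B10 was the member that fell, from 568 ± 13.3 to 460 ± 8.17 CPM. CYP3A4, CYP3A7, ABCB1 and AKR1B10 lie on chromosome 7, where the median log2 change of all tested genes was 0.43.

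Other groups of drug handling genes also rose. Among other cytochrome P450 genes, 14 of 19 rose and 1 fell (median 1.06, adjusted p = 0.00112; adjusted p = 0.0771 with an estimated correlation). CYP2C18 rose from 1.19 ± 0.16 to 91.0 ± 2.26 CPM and the fatty acid hydroxylase gene CYP4A11 from 0.39 ± 0.18 to 23.6 ± 0.73 CPM, while the retinoic acid hydroxylase gene CYP26B1 fell from 7.68 ± 0.22 to 3.25 ± 0.28 CPM. Of 30 conjugating enzyme genes, 22 rose and 4 fell (median 0.72, adjusted p = 0.000217; adjusted p = 0.0673 with an estimated correlation). GSTM1, a glutathione transferase gene, fell from 54.8 ± 2.53 to 0.30 ± 0.25 CPM. Of 21 liver transporters, 15 rose and 4 fell (median 1.57, adjusted p = 0.00112; adjusted p = 0.0940 with an estimated correlation). SLC22A7, an organic anion transporter, rose from 0.53 ± 0.23 to 42.9 ± 0.90 CPM, and the efflux pump gene ABCC4 fell from 61.8 ± 4.68 to 35.7 ± 0.87 CPM.

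Secreted and metabolic functions of hepatocytes followed the same direction. All 37 measured genes for hepatocyte secreted proteins rose (median 3.30, adjusted p = 8.4e-17; 0.0153 as the adjusted p with an estimated correlation). ALB (chromosome 4, 73397114 to 73421412) rose by 5.24 ± 0.037. Of 39 complement and coagulation genes, 38 rose (median 3.40, adjusted p = 8.4e-17; adjusted p = 0.0254 with an estimated correlation), and PROC, for protein C, fell from 12.9 ± 0.71 to 8.81 ± 0.88 CPM. Bile acid synthesis genes rose at 13 of 15 members and fell at 1 (median 1.35, adjusted p = 0.000223; adjusted p = 0.0673 with an estimated correlation). BAAT, which conjugates bile acids, rose from 5.30 ± 0.29 to 201 ± 1.49 CPM, and CYP7A1, the rate-limiting enzyme, rose from 0.058 ± 0.021 CPM, or 3 reads over the 3 wild-type libraries, to 11.8 ± 0.14 CPM.

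Of 29 genes of gluconeogenesis and amino acid breakdown, 23 rose and 6 fell (median 1.61, adjusted p = 7.7e-06; adjusted p = 0.132 with an estimated correlation). AGXT rose from 0.88 ± 0.33 to 102 ± 5.10 CPM, and FAH, for the last enzyme of tyrosine breakdown, fell from 171 ± 1.40 to 113 ± 1.77 CPM. Of 27 genes of fatty acid oxidation and ketogenesis, 23 rose and 3 fell (median 0.57, adjusted p = 7.7e-06; adjusted p = 0.132 with an estimated correlation). BDH1, an enzyme of ketone body metabolism, rose from 0.17 ± 0.096 to 11.6 ± 0.60 CPM, and SLC25A20, the carnitine carrier of mitochondria, fell from 68.3 ± 3.34 to 39.0 ± 0.96 CPM. Of 26 cholesterol synthesis genes, 20 rose and 4 fell (median 0.43, adjusted p = 0.000567; adjusted p = 0.132 with an estimated correlation). INSIG1 rose from 151 ± 3.30 to 380 ± 6.0 CPM. SREBF2, the regulator of the pathway, fell from 129 ± 4.72 to 70.6 ± 3.23 CPM. It lies on chromosome 22, and with the median change of its 20 Mb window taken out its log2 change was -0.0016 (limma adjusted p = 0.976). That median, -0.87, was taken from the same changes, so this value does not test whether SREBF2 changed apart from its window.

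Nuclear receptors and liver transcription factors rose at 23 of 36 members and fell at 7 (median 0.45, adjusted p = 0.0122; adjusted p = 0.252 with an estimated correlation). NR1H4, the bile acid receptor FXR, rose from 2.17 ± 0.39 to 68.7 ± 2.63 CPM, and NR1I3, the constitutive androstane receptor, rose from 0.46 ± 0.052 to 2.12 ± 0.27 CPM. PPARG and RARB fell, from 35.1 ± 0.68 to 16.1 ± 1.40 CPM and from 9.37 ± 0.68 to 2.27 ± 0.35 CPM.

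All 24 p53 target genes rose (median 2.22, adjusted p = 8.0e-13; adjusted p = 0.0154 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 35.1 ± 1.99 to 664 ± 17.3 CPM (log2 4.22 ± 0.038). MDM2 rose by 4.06 ± 0.029 and lies on chromosome 12, where the median log2 change of all tested genes was 0.33. Of 34 cell cycle genes, 32 fell and 2 rose (median -1.32, adjusted p = 7.5e-11; adjusted p = 0.0154 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell from 123 ± 4.10 to 19.99 ± 0.71 CPM, and MCM5, a subunit of the replicative helicase encoded on chromosome 22, fell from 105 ± 3.75 to 14.2 ± 0.86 CPM. TYMS and PCNA were the members that rose, by 0.68 ± 0.060 and 0.23 ± 0.031. Of 44 ribosomal protein genes, 43 fell and none rose (median -0.88, adjusted p = 9.7e-16; adjusted p = 0.0940 with an estimated correlation). RPL3, on chromosome 22, fell from 1500 ± 0.68 to 543 ± 10.3 CPM.

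**Figure D3:**
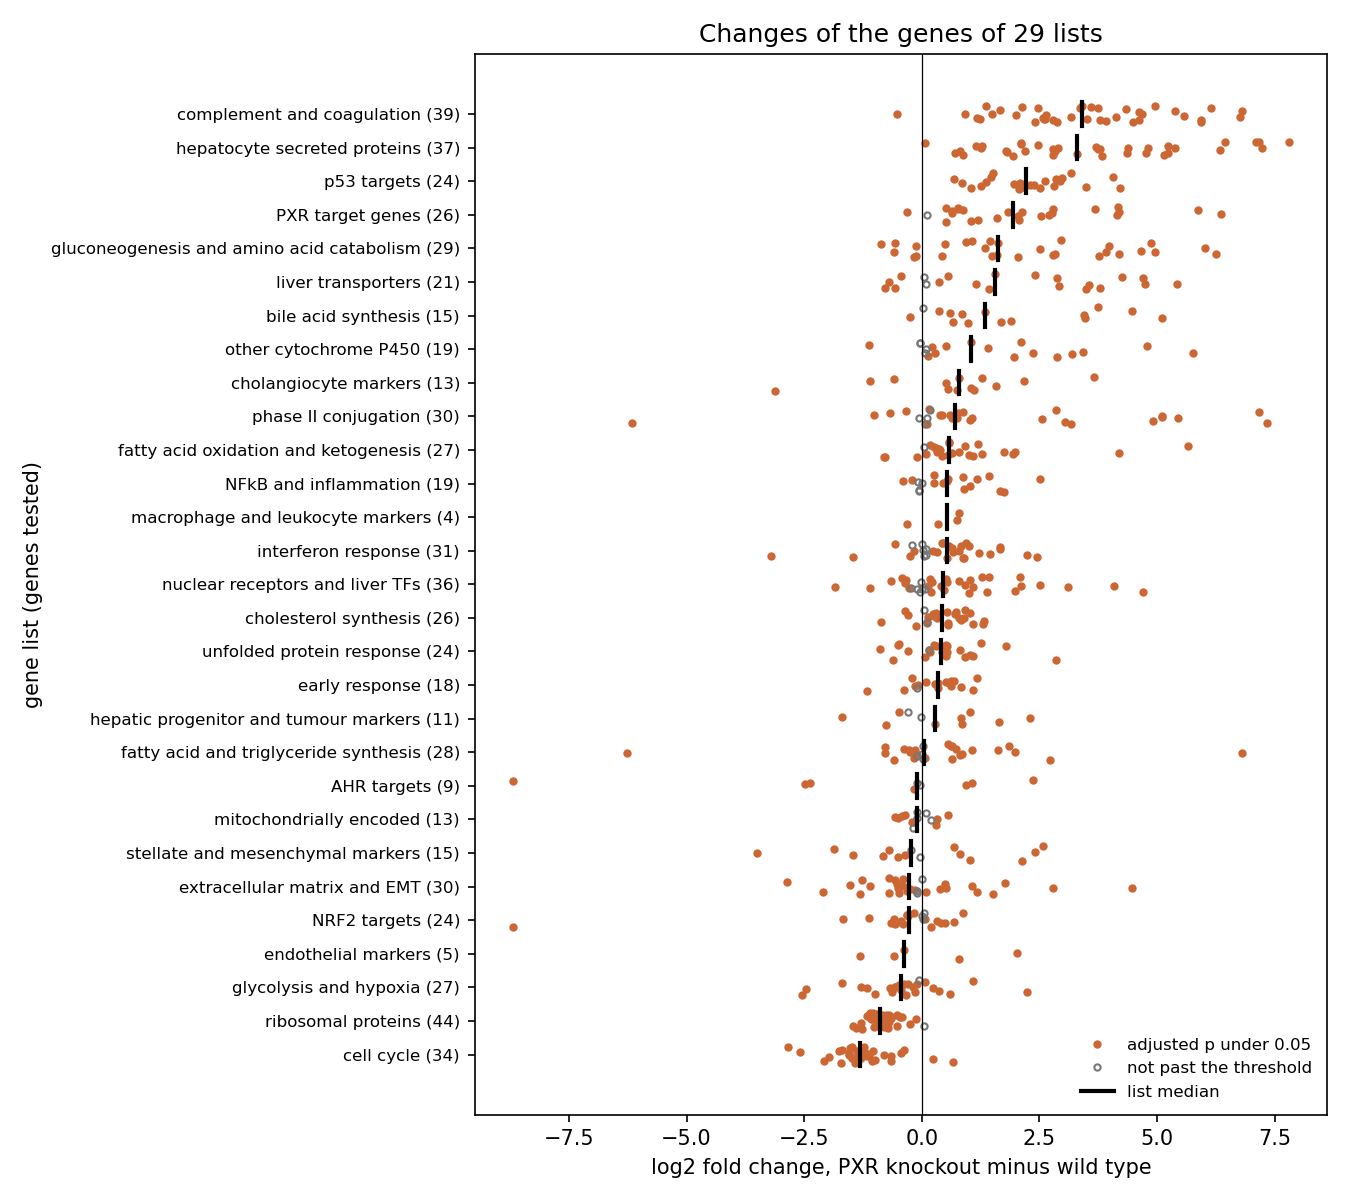
Log2 fold change (knockout minus wild type) of each tested gene of the 29 lists fixed before the data were examined, with the number tested in brackets; filled points have an adjusted p under 0.05, open points do not, and black bars are list medians. Medians run from 3.40 for complement and coagulation to -1.32 for the cell cycle.

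Stress and signalling lists had medians between -0.44 and 0.55. Glycolysis and hypoxia genes fell at 20 of 27 members and rose at 6 (median -0.44, adjusted p = 0.00438; adjusted p = 0.395 with an estimated correlation), with ALDOC falling from 318 ± 10.4 to 53.7 ± 1.42 CPM and PFKP rising from 1.63 ± 0.090 to 9.60 ± 1.19 CPM. NF-κB and inflammation genes rose at 13 of 19 members and fell at 2 (median 0.55, adjusted p = 0.00451; adjusted p = 0.0935 with an estimated correlation). The chemokine gene CXCL2 rose from 5.51 ± 0.47 to 33.8 ± 1.62 CPM. Of 31 interferon response genes, 20 rose and 5 fell (median 0.53, camera adjusted p = 0.0146, and adjusted p = 0.160 with an estimated correlation). Among them, MX1 rose from 4.06 ± 0.97 to 20.7 ± 0.77 CPM, and IFI27 fell from 15.7 ± 0.37 to 1.26 ± 0.16 CPM. Of 24 genes of the unfolded protein response, 18 rose and 5 fell (median 0.41, adjusted p = 0.00610; adjusted p = 0.132 with an estimated correlation). SESN2, also counted among the p53 targets, rose from 9.83 ± 0.71 to 74.3 ± 1.73 CPM. Early response genes rose at 12 of 18 members and fell at 5 (median 0.34, adjusted p = 0.0266; adjusted p = 0.415 with an estimated correlation); this call was also lost with quantile normalization (adjusted p = 0.0514). DUSP1 rose from 243 ± 4.52 to 547 ± 7.10 CPM.

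Of the lists of markers of other cell types, only that of bile duct cells passed camera. Of 13 cholangiocyte markers, 10 rose and 3 fell (median 0.79, adjusted p = 0.0188; adjusted p = 0.132 with an estimated correlation). KRT19, a bile duct keratin, rose from 111 ± 2.89 to 334 ± 12.2 CPM, and SPP1, for osteopontin, fell from 382 ± 12.4 to 43.6 ± 1.46 CPM. Of 15 stellate and mesenchymal markers, 6 rose and 7 fell (adjusted p = 0.972), with a median of -0.23, a mean of 0.012 and an upward camera direction. DCN rose from 63.1 ± 2.61 to 335 ± 9.40 CPM and COL5A1 fell from 185 ± 5.81 to 50.8 ± 3.62 CPM. Of 5 endothelial markers, 2 rose and 3 fell (camera adjusted p = 0.741), with a median of -0.37, a mean of 0.11 and an upward camera direction. KDR rose from 53.3 ± 0.20 to 218 ± 3.93 CPM. Of the 22 macrophage and leukocyte markers only 4 passed the filter, too few to test, and 3 of them rose and 1 fell.

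The remaining lists did not pass the threshold. NRF2 targets fell at 14 of 24 members and rose at 7 (adjusted p = 0.0660), with NQO1 and SLC7A11 (135 ± 1.30 to 41.7 ± 0.90 CPM) falling most. Aryl hydrocarbon receptor targets split into 3 that rose and 4 that fell of 9 (adjusted p = 0.477), with a median of -0.10 and a mean of -1.05 that includes NQO1; CYP1A1 rose from 2.98 ± 0.027 to 17.4 ± 0.73 CPM. Matrix and epithelial-mesenchymal transition genes rose at 10 and fell at 17 of 30 members (adjusted p = 0.193), with the epithelial cadherin gene CDH1 rising from 1.79 ± 0.55 to 49.3 ± 1.17 CPM and the protease gene MMP2 falling from 20.004 ± 0.72 to 2.32 ± 0.29 CPM. Fatty acid and triglyceride synthesis genes rose at 14 and fell at 10 of 28 (adjusted p = 0.1999). The median of that list was 0.048 and turned to -0.065 with quantile normalization, to -0.090 with libraries scaled to equal sums and to -0.11 with equal sums without small RNA genes. Progenitor and tumour markers rose at 6 and fell at 3 of 11 (adjusted p = 0.354), CD44 rising from 22.8 ± 1.58 to 72.6 ± 1.17 CPM. Mitochondrially encoded genes rose at 3 and fell at 5 of 13 (adjusted p = 0.521).

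Of the 28 lists tested, 20 passed with the preset correlation, 17 upward and 3 downward, and 5 of them held with an estimated correlation: PXR targets, secreted proteins, complement and coagulation, p53 targets and the cell cycle. Counts of risen and fallen members adjusted over the list alone were equal to those over all genes for 26 lists.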

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

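The pseudocount of 0.1, voom weights, thinned reads, scaling to equal sums with and without small RNA genes, correction for their share and removal of window medians were chosen after seeing the data. Over all 22 alternatives for genes, 12043 to 13170 genes passed, with 5255 to 6667 higher, 5979 to 7873 lower and 3272 to 4140 changed by at least 2-fold; NR1I2 stayed higher at 0.65 to 0.85. Leaving out each library in turn gave 12444 to 12887 genes, 6267 to 6494 higher, 6177 to 6393 lower, 3691 to 3724 by at least 2-fold, 0.74 to 0.85 for NR1I2 and 20 lists. With an estimated correlation 5 lists passed in place of 20. NF-κB, other cytochrome P450, bile acid synthesis and cholangiocyte lists lost the call at estimates of -0.0035, 0.0044, 0.0075 and 0.0083. These lie below the preset 0.01, so a larger correlation between genes does not account for their loss. The camera adjusted p also rose for lists that held. It went from 8.4e-17 to 0.0153 for secreted proteins at an estimate of -0.00088. For PXR targets it went from 1.8e-09 to 0.0154 at -0.0012. The preset and the estimated setting of camera therefore differ in more than the correlation. The other lists that were lost had estimates above 0.01, where that difference was not told apart from a larger correlation. For named genes, 2729 of 2745 values kept direction and side, 15 lost the call and 1 reversed: ATF4, on chromosome 22, went from -0.62 to 0.11 with window medians taken out, a construction that adds back the shift of its window. The lost calls were those of TIE1, CD14, MT-CO3, SREBF2 and SDF2L1. NRF2 targets passed as lower under 5 alternatives. The replicate number as a block gave 12916 genes, 12823 of them shared, and 20 lists; same-numbered libraries correlated at -0.061 to 0.025, so the numbers do not pair them. With reads thinned to the shallowest library 12193 genes passed, so the deeper knockout libraries did not set the count. Depth limits genes near the floor, where 3 reads are worth 0.092 to 0.25 CPM.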

Other observations

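Of 12 gene families that were not fixed as lists and were counted too, 10 are reported here; all of them were chosen after the data were seen, and none was tested for enrichment. All 5 SPANX genes tested fell (median -4.00), as did 5 of 6 MAGEA and MAGEB genes (median -3.06), both families of cancer-testis antigens on chromosome X; MAGEA1 went from 141 ± 7.08 to 7.54 ± 0.13 CPM (SD, n = 3) and MAGEA11 rose from 0.62 ± 0.043 to 3.04 ± 0.63 CPM. Of 48 histone genes of the HIST clusters, 42 fell and 2 rose (median -0.99). All 6 UGT2B genes, which are also in the conjugation list, and 6 of 7 SERPINA genes, some of them also in the list of secreted proteins, rose (medians 5.18 and 2.80). The medians of these 5 families kept their sign under centring, quantile normalization and scaling to equal sums without small RNA genes. The other families reported here were mixed: APOBEC3 genes rose at 4 and fell at 1 of 6, cadherins rose at 7 and fell at 5 of 12, EPHA and EPHB receptors rose at 6 and fell at 5 of 12, HOX genes rose at 2 and fell at 3 of 6, and ZNF genes rose at 140 and fell at 171 of 412. SPANX, MAGEA and histone genes have near-identical copies that share reads, so their levels are uncertain.

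The tests of the chromosome pattern were set before their results were seen, except the rotations and shuffles for chromosomes 7 and 12; those and the tests of the other patterns and of the splits were chosen after. Genes of chromosome 22 were lower in the knockout (median log2 change -0.77, 95% bootstrap interval -0.87 to -0.70, 83.6% of 377 genes lower), and those of chromosomes 7 and 12 higher (0.43 and 0.33). Medians of 20 Mb windows were 0.33 to 0.54 over all 8 windows of chromosome 7; on chromosome 12 they were -0.044 and -0.050 up to 40 Mb and 0.38 to 0.55 beyond it; windows of 0 to 40 Mb on chromosomes 9 (0.43 and 0.45) and 11 (0.32 and 0.59) and of 0 to 20 Mb on chromosome 17 (0.43) were also raised. Local regression on GC content, length and level left at least 100.7% of the shift (lower bootstrap limit 75.4%), which argues against those biases. For chromosome 22, chance placement is argued against by 10000 rotations of the changes along the genome (permutation p = 0.0194). For the second and the third largest median, those of chromosomes 7 and 12, the same rotations did not pass (permutation p = 0.101 and 0.147). Rotations carry shifted chromosomes along whole. In 10000 shuffles of 20 Mb windows the values were 0.0025 and 0.0008 (permutation p). Shuffles break up runs of neighbouring windows that move together, so a small p is easier to reach. Chance placement is therefore left open for chromosomes 7 and 12. At least 70.0% of genes on each of the 3 chromosomes lay on the side of its shift. These chromosomes had the largest absolute medians of the same changes. A majority on that side was therefore given in advance and does not test copy number. On chromosome 12 the windows up to 40 Mb were not raised, which a different copy number of the whole chromosome would not give. A different copy number of chromosomes or of their parts in the cells of each group remains a hypothesis, since no DNA was analysed here. With window medians taken out 12767 genes and 20 lists passed.

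Another pattern is that PXR targets and other liver genes were higher in the libraries labelled knockout. Depth and scaling are argued against, since the list median stayed at 1.78 or more under thinning and other scalings. If loss of PXR held its targets below other drug metabolism genes, their median change would be lower, which was not seen. The PXR list lay 0.98 above the pooled cytochrome P450, conjugation and transporter lists. That difference did not pass 0.05 (26 against 70 genes, two-sided permutation p = 0.174, genes not being independent replicates), so the question is left open. A difference between the cells other than PXR, such as their state of differentiation or origin as separate lines, cannot be told apart from the genotype, because there is 1 kind of cell per genotype. The first component held 96.4% of the variance and separated the groups, which does not tell these apart. An exchange of the labels of the groups, which would reverse every direction given here, is not excluded by NR1I2 at 0.80 either, and an effect of PXR loss itself stays open.

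A further pattern is that 11 genes were above 50 CPM in wild type and under 2 CPM in the knockout, and 35 genes the other way. The 11 include NQO1, MIF, GSTM1 and EPHA5 (57.2 ± 0.89 to 0.24 ± 0.075 CPM), of which EPHA5 is outside the naming rule. Loss of a wider segment is left open: among the 22 nearest tested protein-coding neighbours, 5 of the 11 genes had at least 1 with a log2 change below -1 (NES had 2, at -1.04 and -1.37, and MIF had GSTT2B at -2.92), and 6 genes had none. Over all 16219 tested genes, 1636 passed with a fall of at least 2-fold. The lowest neighbour, GSTT2B, fell less than any of the 11, of which KCNQ3 at -4.92 fell least. For GSTM1, reads moved to related genes are argued against as the main cause, since GSTM2 and GSTM3 together gained 9.91% of the level that GSTM1 lost and GSTM4 fell from 133 ± 1.18 to 105 ± 3.53 CPM. Deletions of single genes and silencing may each account for part of the 11 and were not tested.

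The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 12960 genes past the threshold and 3686 by at least 2-fold, and the highest of the other splits gave 0 and 0. By list, the real split gave 20 and the other splits 14 to 20. Every other split mixes libraries of both groups on each side. The difference between the groups then swells the spread within a side, which holds gene counts down. Part of that difference also stays between the sides, so lists can still pass. The splits therefore cannot decide whether chance gave these counts. As large a result was reached by 1 split for each gene count, the real one, and by 2 splits for lists.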
